A study of Mus musculus with 18 samples.

How the data were processed

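RNA sequencing was analysed in 18 libraries of E2-10HA, a mouse T cell hybridoma line. Per the labels' protocols, total RNA was isolated on columns with DNase treatment, and stranded libraries were prepared from ribosome-depleted RNA, so transcripts without a poly(A) tail were measured as well. In the knockdown experiment, 3 libraries came from cells carrying a lentiviral hairpin (shRNA) against L3MBTL3 and 3 from cells carrying a scramble hairpin. In the rescue experiment, cells depleted of RBPJ were infected with an empty vector, with Flag-tagged mouse RBPJ, or with the F261A/A284V form of it, and 4 libraries were made per group. A single hairpin was used, and its effect cannot be set against a second hairpin here.

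The authors deposited 1 table of values per experiment, each with 24391 genes by symbol. Per the submitters' processing notes, TopHat2 2.1.1, DESeq2 1.24.0 and the mouse build mm9 were used; the read counter, its gene annotation and its handling of strand are not given in the sources used here. The values behave as a signal made by the authors from gene counts, each divided by 1 size factor per library: within every library, 100% of the values came out as whole multiples of the value of 1 read, within a tolerance of 0.1 read. The recovered reads summed to between 4882485 and 6129134 per library in the knockdown table. In the rescue table they summed to between 5923799 and 7921533 in replicates 1 and 2, and to between 3553505 and 4239479 in replicates 3 and 4. The tables were normalized separately by the authors, so tests were run within a table only. Genes were named by the symbols of the tables. No coordinates are given, since the annotation of mm9 was not used here; gene order, GC content and gene length came from an annotation of the build GRCm38. Genes that overlap, run antisense to each other or belong to families with near-identical copies share an uncertain number of reads, and 56 tested genes of the knockdown table and 58 of the rescue table held the same values as another gene.

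Genes with a normalized value of at least 10 in at least 3 libraries (knockdown) or 4 libraries (rescue) were tested, 11586 and 11691 genes. Log2(value + 1) was compared with limma 3.58.1 (limma-trend, 2-sided) in R 4.3.3, with group as the only term, and the rescue comparisons came from 1 fit to all 12 libraries. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison, and every adjusted p of a gene is from limma unless another tool is named. The labels do not say that replicates came from separate cultures or infections, so p-values measure only the spread between these samples, which may be technical.

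Replicate numbers are shared between the groups, and whether they pair the libraries was checked by correlating the libraries' deviations from their group means across genes. Same-numbered libraries correlated at 0.28 to 0.60 in the knockdown and at 0.71 to 0.91 in the rescue. A fit with the replicate number as a block (the paired fit) is therefore given beside the results it changes. In the knockdown, replicate 3 stood apart, at -0.21 to -0.59 with the other group's libraries of other numbers. L3MBTL3 shRNA replicate 1 and scramble replicate 2 correlated at 0.45, above the 0.28 of the replicate 2 pair. L3MBTL3 shRNA replicate 2 and scramble replicate 1 correlated at 0.079. Pairing of replicates 1 and 2 by number is thus uncertain there. In the rescue table, replicates 1 and 2 stood apart from replicates 3 and 4: libraries of different groups correlated at no more than -0.61 across that divide, and the first principal component held 73.1% of the variance. On each side of it, libraries of different groups correlated at 0.71 or more whatever their number. The numbers thus show no pairing in the rescue beyond this divide. This divide is treated as a batch, and values within replicates 1 and 2 and within replicates 3 and 4 are given.

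Recovered reads of each pair of libraries in a group were compared by a chi-square test over genes. Empty vector replicates 1 and 2 differed by less than sampling noise (chi-square per degree of freedom 0.849), as did RBPJ WT replicates 1 and 2 (0.692) and F261A/A284V replicates 3 and 4 (0.826), while other pairs of the same groups differed by more (1.06 to 18.2). Each of these pairs was averaged and counted as 1 sample, so means ± SD of the rescue groups are over 3 samples. Whether these pairs are 1 library sequenced again is not given in the sources used here; removal of duplicate reads before counting, which lowers the noise, could also give values below 1. The n, SD and merged p of the rescue groups rest on this choice. Empty vector replicates 3 and 4, at 1.06, differed by slightly more than sampling noise and were kept apart. The test fixed in advance keeps all 12 libraries and so counts these pairs separately. A fit to the 9 merged samples with the batch as a term (the merged fit) is therefore given beside the rescue results. It also takes out the batch, which the merged groups hold in unequal numbers, and it was added after seeing the data. Because the batch weighs unequally in the merged means, ratios of the printed means can differ from the fitted fold changes, also in direction. No group then had 4 samples, so no sample was tested as an outlier of its group.

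The named genes were chosen by a rule fixed in advance: L3mbtl3 and Rbpj; the 10 largest positive and 10 largest negative fold changes among called genes whose libraries do not overlap between the groups and whose mean is at least 50 in either group, passing over predicted gene models; measured Notch target genes; up to 4 members of each other list with the smallest p; and genes called alike in the knockdown and in F261A/A284V against RBPJ WT. Other genes named were chosen after their values were seen. The results of some genes are not reported here.

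Gene lists written before the data were examined covered Notch and RBPJ target genes, the Notch pathway, RBPJ corepressors, the malignant brain tumour (MBT) domain family, T cell identity, T cell activation, the type I interferon response, p53 targets, the cell cycle, ATF4 targets, cholesterol synthesis, glycolysis and hypoxia, apoptosis, chemokines and adhesion, stress and immediate early genes, replication-dependent histones, and markers of B cells, myeloid cells, NK and innate lymphoid cells, and stroma. A list of mitochondrially encoded genes had no tested member. Lists were tested with camera (limma, preset correlation 0.01, Benjamini-Hochberg over 16 lists per comparison), again with an estimated correlation, and by counting called members over all genes and adjusted over the list alone. The version with an estimated correlation also rests on the few residual degrees of freedom. A call lost there need not reflect correlation between genes: the Notch pathway list lost its call with the hairpin at an estimated correlation of -0.0162. The marker lists of other cell types had fewer than 5 tested members and were only counted. Gene sets from one experiment were tested in the other with camera, with Benjamini-Hochberg adjustment over the 6 tests of hairpin sets in the rescue, and over the 1 or 2 tests of RBPJ WT sets in the knockdown. The response to the mutant as a share of the response to RBPJ WT was a slope over genes chosen in replicates 1 and 2 and measured in replicates 3 and 4, then exchanged, with a 95% interval over 2000 bootstrap draws of genes.

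Alternatives fixed in advance were other pseudocounts and filters, quantile and upper quartile scaling, library weights, the paired fit, only the groups compared, leaving out each library, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Added after seeing the data were the batch term, each batch alone, the merged fits, removal of GC and length trends, and edgeR with the block. The scripts were tested on simulated data with known fold changes. In a simulation of the knockdown, 79.1% of genes changed 2-fold were recovered without the block and 95.5% in the paired fit. For RBPJ WT against the empty vector these shares were 71.6% and 100%. Unchanged genes called numbered 0 without the block in both, and 10 and 4 in the paired fit. The simulation gave same-numbered libraries the same means and drew each library independently, so pairing was built in. It cannot show that the paired fit gains as much in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.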

Results

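Gene expression was measured by sequencing of ribosome-depleted total RNA in E2-10HA, a hybridoma line described as mature mouse T cells. RBPJ is the DNA-binding factor through which Notch receptors switch on their target genes, and without Notch it can hold them down together with corepressors. L3MBTL3, a protein with MBT domains that bind methylated lysines, has been described as a partner of RBPJ. The knockdown experiment asked which genes change when L3MBTL3 is targeted by a hairpin, with 3 libraries per group. The rescue experiment put back RBPJ WT or RBPJ F261A/A284V into cells depleted of RBPJ, with an empty vector as control and 4 libraries per group; both substitutions lie in the domain of RBPJ that contacts Notch and several corepressors. Recovered reads per library ranged from 4882485 to 6129134 in the knockdown and from 3553505 to 7921533 in the rescue. Empty vector replicates 1 and 2, RBPJ WT replicates 1 and 2, and F261A/A284V replicates 3 and 4 differed by less than sampling noise. Each of these pairs was counted as 1 sample in means and SDs. Fold changes and adjusted p of the rescue come from the fit to all 12 libraries unless another fit is named. That fit counts these pairs separately, so its p-values do not rest on the n printed with the means.

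In the knockdown experiment, the transcript of L3mbtl3 itself was hardly lower. Its normalized values were 467, 447 and 352 in scramble replicates 1, 2 and 3 and 394, 371 and 370 in the libraries labelled L3MBTL3 shRNA. The means were 422 ± 61.8 and 378 ± 13.8 (SD, n = 3 each), a log2 fold change of -0.15 (SE 0.107, adjusted p = 0.402; 0.203 in the paired fit). The scramble library of replicate 3 lay below every library labelled L3MBTL3 shRNA, which goes against its label. Rbpj averaged 1609 ± 111 with the hairpin and 1838 ± 286 with scramble (adjusted p = 0.312). The directions below are therefore those of the labels.

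Of 11586 genes tested, 256 rose and 129 fell in the libraries labelled L3MBTL3 shRNA against scramble, 51 and 5 of them at least 2-fold. Abca1, which exports cholesterol from cells, rose to 59.6 ± 21.5 from 13.2 ± 7.43 (log2 2.17, adjusted p = 0.0387). The galactosyltransferase gene B3galt5 rose to 185.5 ± 78.6 from 39.6 ± 13.8 (log2 2.16), and Abat, which breaks down the transmitter GABA, to 273 ± 74.5 from 76.6 ± 28. Ccdc80, a secreted matrix protein, rose to 198 ± 55.6 from 66 ± 18.6 (log2 1.56, adjusted p = 0.0343). The interleukin-6 receptor gene Il6ra rose to 99.9 ± 10.2 from 35.1 ± 11.5 (log2 1.53). Cth, which makes cysteine, fell to 62.3 ± 9.84 from 189 ± 59.2 (log2 -1.55, adjusted p = 0.0314), and Galnt3, which starts O-linked sugar chains on mucin-type proteins, to 167 ± 13.4 from 310.6 ± 15.5 (log2 -0.89, adjusted p = 0.0236).

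Among called genes with a mean of at least 50 in either group and no overlap between the groups, predicted gene models aside, the other genes with the largest rises were Fbxo10 (log2 1.71), a subunit of ubiquitin ligases, Abhd15 (1.67), the phospholipase gene Plce1 (1.66), Skida1 (1.63) and the cilium gene Dzip1 (1.52). The other largest decreases by the same rule were those of Syngr4 (log2 -1.31), the Wnt pathway gene Frat2 (-1.12), the cation transporter gene Slc22a3 (-1.10), the lymphotoxin gene Lta (-0.95), Tstd1 (-0.90), the lipase gene Lipg (-0.88), the microRNA host gene Mirc35hg (-0.87) and the lectin receptor gene Clec4d (-0.86). Adjusted p of these genes lay between 0.0306 (Fbxo10, Dzip1) and 0.0489 (Abhd15).

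Of 26 tested genes of the Notch pathway, 3 rose over all genes tested and 7 when adjusted over the list alone, and camera placed the list above other genes (adjusted p = 0.0176; adjusted p = 0.578 with an estimated correlation). These were Rfng, a glycosyltransferase that modifies Notch receptors (171 ± 12.1 against 90 ± 14.2, log2 0.93), the receptor gene Notch2 (3071 ± 97.2 against 2327 ± 111, log2 0.40) and the coactivator gene Maml3 (548 ± 70.1 against 360 ± 32.5, log2 0.60). Of 17 tested Notch target genes, only Lgmn rose over all genes tested; adjusted over the list alone, 4 rose and 2 fell, and camera did not separate the list from other genes (adjusted p = 0.748). Lgmn, a lysosomal protease, stood at 26.5 ± 12.2 with the hairpin and 1.89 ± 1.64 with scramble (log2 3.36, adjusted p = 0.0379), near the detection floor in the latter. Hes1, a classical Notch target, averaged 279 ± 81.4 against 194 ± 72.6 (adjusted p = 0.252) and passed in the paired fit (adjusted p = 0.00207), where Bcl6, Jag1, Notch1 and Trib2 also rose and Cdca7 and Tcf7 fell.

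Among 30 genes of the cell cycle, Cdc20 (log2 -0.49), Cdc6 (-0.39), E2f2 (-0.41), Mcm3 (-0.30) and Rrm2 fell. Adjusted over the list alone, 23 fell and 0 rose, and camera gave an adjusted p = 1.01e-11 (adjusted p = 0.647 with an estimated correlation). Of 19 ATF4 targets of the amino acid stress response, only the folate enzyme gene Mthfd2 fell over all genes (log2 -0.31), and 11 fell when adjusted over the list alone (camera adjusted p = 4.77e-07; adjusted p = 0.647 with an estimated correlation). The stress and immediate early genes, of which none of 11 passed over all genes or over the list alone, and the 20 replication histones, likewise with none, lay lower by camera (adjusted p = 0.00696 and 0.00761; adjusted p = 0.735 for each with an estimated correlation). In the paired fit, 7 of the stress and immediate early genes fell, Fos, Jun and Dusp1 among them, while no histone gene passed.

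T cell genes moved both ways. Cd4, the coreceptor of helper T cells, rose to 47.4 ± 8.21 from 11.8 ± 2.12 (log2 1.92, adjusted p = 0.0306), Runx1 rose by a log2 fold change of 0.32, and Ccr7, a lymph node homing receptor, fell to 6.45 ± 0.604 from 35.5 ± 14.4 (log2 -2.22, adjusted p = 0.0314). The other 22 of 25 T cell identity genes did not pass, adjusted over the list alone the count was the same 2 up and 1 down, and camera gave an adjusted p = 0.304. Of 18 activation genes, the cytokine gene Tnf and the early activation marker Cd69 fell (log2 -0.43 and -0.42), 4 fell when adjusted over the list alone, and camera gave an adjusted p = 0.253. The RNA sensor gene Ddx58 rose (log2 0.74) as 1 of 23 interferon response genes (also 1 over the list alone; camera adjusted p = 0.304), and Btg2, an antiproliferative gene, rose (log2 0.47) as 1 of 16 p53 targets (1 up and 1 down over the list alone; camera adjusted p = 0.92). Mbtd1 fell (log2 -0.40) as 1 of 12 genes of the MBT family (1 up and 1 down over the list alone; camera adjusted p = 0.514), and Ccr7 was the only called gene of 19 for chemokines and adhesion (2 up and 3 down over the list alone; camera adjusted p = 0.429).

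No gene passed over all genes in the lists of RBPJ corepressors (17 tested, 0 over the list alone, camera adjusted p = 0.478), cholesterol synthesis (19 tested, 0 over the list alone, 0.191), glycolysis and hypoxia (24 tested, 0 over the list alone, 0.429) and apoptosis (19 tested, 1 up and 3 down over the list alone, 0.492). In the paired fit, 4 cholesterol genes fell (camera adjusted p = 0.0325; adjusted p = 0.591 with an estimated correlation). Among markers of other cell types, Tbx21 rose (log2 0.59) as 1 of 3 tested for NK and innate lymphoid cells, a gene that T cells also express, and none of 4 tested for B cells, 2 for myeloid cells or 2 for stroma passed over all genes. The myeloid markers Cd68 and Fcgr3 were lower when adjusted over that list alone.

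With the paired fit, 1566 genes rose and 1009 fell, all 385 of the genes named above or counted with them included. The rising share of the calls was 66.5% as tested, 60.8% in the paired fit, 58.6% after quantile scaling, 57% with library weights, and 42.7% (1188 up, 1595 down) in the paired fit after removal of GC and length trends. The groups did not overlap in 35.2% of tested genes, where 10% is the share by chance if the libraries are exchangeable. The unpaired calls depend on single libraries: limma called no gene without replicate 1 or 2 labelled L3MBTL3 shRNA or without scramble replicate 2 (1683, 1893 and 2926 genes at an unadjusted p under 0.05; 0 in each case by edgeR), and 5 without replicate 3 labelled L3MBTL3 shRNA. Without scramble replicate 1, 223 of the 385 calls were kept, and without scramble replicate 3 all were, with 644 genes up and 378 down. In the paired fit, 10 genes of the Notch pathway rose, while 23 of the cell cycle and 12 ATF4 targets fell. There, 6 rose and 2 fell for interferon and for T cell identity, 2 and 6 for T cell activation, 2 and 4 for apoptosis, 3 and 6 for chemokines and adhesion, 4 and 2 for p53 targets, 1 and 3 for glycolysis and hypoxia and 1 and 1 for the MBT family. The corepressor gene Cir1 (log2 -0.38), Prdm1 from the B cell markers (-0.21) and the myeloid markers Cd68 (-0.38) and Fcgr3 (-0.84) also fell there.

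**Figure D1:**
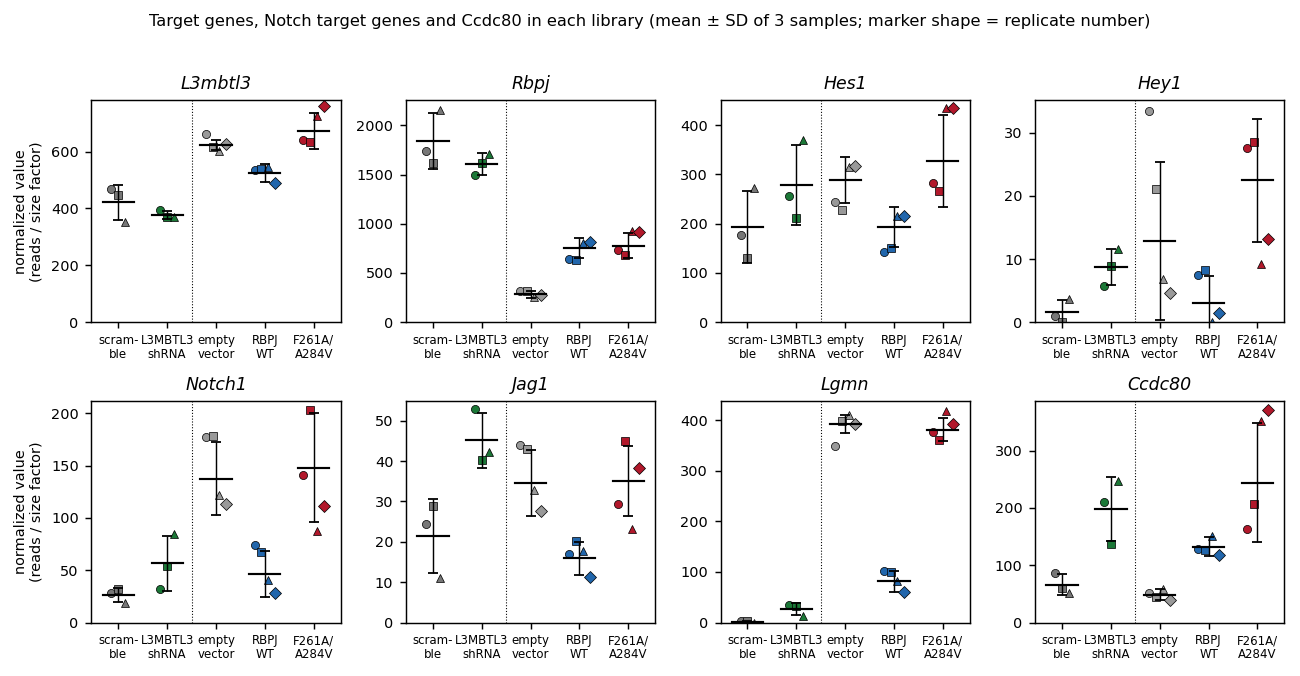
Normalized values (read count divided by size factor, linear axes) of 8 genes in each of the 18 libraries; marker shapes give the replicate number, and horizontal and vertical bars are mean ± SD over 3 samples, near-identical libraries counted once. The dotted line parts the tables, which were normalized separately; L3mbtl3 in scramble replicate 3 (352) lies below all libraries labelled L3MBTL3 shRNA, and Lgmn averages 81.5 with RBPJ WT against 392 with the empty vector and 381 with the mutant.

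In the rescue experiment, RBPJ WT against the empty vector showed which genes are lowered or raised when RBPJ is put back. Rbpj rose to 752 ± 101 from 281 ± 32.1 (SD, n = 3 each), with log2 1.31 and adjusted p = 0.000475 in the fit to all 12 libraries. Among those that fell were the Gimap genes, which encode a family of GTPases that act in lymphocyte survival. Gimap8 fell to 3.58 ± 0.901 from 77.6 ± 3.01 (log2 -4.11, SE 0.252, adjusted p = 1.14e-05), and Gimap1 to 30.5 ± 7.86 from 409 ± 66.6 (log2 -3.55). Gzmb, the cytotoxic protease granzyme B, fell to 39 ± 4.09 from 298.5 ± 81.1 (log2 -2.73, adjusted p = 0.00111), and Lgmn to 81.5 ± 20.4 from 392 ± 17.9 (log2 -2.18, adjusted p = 1.77e-05). Sgsh, a lysosomal enzyme that degrades heparan sulfate, rose to 175 ± 6.6 from 82.2 ± 9.2 (log2 1.08, adjusted p = 0.00378).

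All 8 tested Gimap genes fell. Besides Gimap8 and Gimap1, the log2 fold change was -4.02 for Gimap6, -3.91 for Gimap4, -3.76 for Gimap5, -3.57 for Gimap3, -3.26 for Gimap7 and -1.37 for Gimap9. Reads of these related genes can be shared between family members. Cd6, a T cell surface receptor, fell to 11.9 ± 2.73 from 57.5 ± 11.7 (log2 -2.20), and the kinase gene Prkch to 21.2 ± 7.57 from 92.7 ± 24.2 (log2 -2.09, adjusted p = 0.0395 for each). Ccdc80 rose to 133 ± 17.2 from 48.9 ± 9.59 (log2 1.42), and Cd200r1, an inhibitory receptor, to 345 ± 39.6 from 235 ± 14.8 (log2 0.53, adjusted p = 0.0395 for each). L3mbtl3 averaged 524 ± 30.6 with RBPJ WT and 623 ± 17.5 with the empty vector (log2 -0.25, adjusted p = 0.588; 0.0654 in the merged fit). It fell in the paired fit (adjusted p = 0.0221).

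Of 20 tested Notch targets, only Lgmn fell over all genes tested, 3 fell when adjusted over the list alone, and camera placed the list below other genes (adjusted p = 5.15e-05; adjusted p = 0.0131 with an estimated correlation). In the merged fit 5 fell: Lgmn, Hes1 (193 ± 40.3 against 289 ± 46.2, adjusted p = 5.48e-05), Notch1 (46.5 ± 21.9 against 137.5 ± 35, adjusted p = 1.23e-06), Hey1 and Jag1. Spen, a corepressor of RBPJ, fell to 976 ± 46.3 from 1330 ± 22.9 (log2 -0.44, adjusted p = 0.00769) as the only one of 17 corepressors (also 1 over the list alone; camera adjusted p = 0.366). No interferon response gene of 27 passed over all genes or over the list alone, while camera placed the list lower (adjusted p = 5.15e-05; adjusted p = 0.356 with an estimated correlation), and Ifih1 and Xaf1 fell in the merged fit. Rbpj was the only called gene of 26 in the Notch pathway (1 up and 2 down over the list alone; camera adjusted p = 0.934).

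Cd6 was the only called gene of 26 for T cell identity (2 down over the list alone; camera adjusted p = 0.366), and Cd28, the costimulatory receptor, fell while Cd4 rose in the merged fit. Gzmb was the only called gene of 18 for T cell activation (1 over the list alone; camera adjusted p = 0.293). Among 19 chemokine and adhesion genes none passed over all genes or over the list alone, but the chemokine receptor genes Ccr2, Ccr4, Ccr8 and Cxcr6 rose in the merged fit (camera adjusted p = 0.00752; adjusted p = 0.233 with an estimated correlation; 0.0157 and 0.217 in the paired fit). The histone list lay lower in that fit too (camera adjusted p = 0.000403; adjusted p = 0.802 with an estimated correlation; 0.000266 and 0.819 in the paired fit), with no member called. For the 14 lists other than Notch targets and interferon, camera gave adjusted p between 0.181 and 0.934 without the batch term. Of the markers of other cell types, 12 in all were tested and none passed over all genes; Itgam, an integrin of myeloid cells that T cells can also express, was lower over its list alone and in the merged fit (12.7 ± 4.25 against 44.8 ± 19).

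In all, 4 genes rose and 25 fell of 11691 tested. In the merged fit 78 rose and 100 fell, all 29 among them, and in the paired fit 116 rose and 145 fell (44.4% up against 13.8%; 25.7% after quantile scaling). Among genes of the lists, Aph1b, Notch1 and Jag1 of the Notch pathway and Zmat3 fell in the paired fit, Nr4a2 and Bbc3 rose, T cell identity held 2 up and 3 down, and Ifih1 was the only interferon gene called. Zmat3 and Nr4a2 were not called in the merged fit. With near-identical libraries merged and no batch term, 2 rose and 11 fell. Within replicates 1 and 2 alone, 47 rose and 70 fell, although both groups then hold a single sample once near-identical libraries are counted once, and within replicates 3 and 4, 64 rose and 81 fell. The log2 fold changes in the respective batches were -4.06 and -4.16 for Gimap8, -1.87 and -2.49 for Lgmn and -2.31 and -3.15 for Gzmb. The total of 29 dropped to 19 without RBPJ WT replicate 1, RBPJ WT replicate 3 or empty vector replicate 2, to 18 without empty vector replicate 3 and to 17 without empty vector replicate 4. The libraries of the 2 groups did not overlap in 3.34% of tested genes. This share was 1.92% for the mutant against the empty vector and 3.7% for the mutant against RBPJ WT. Exchangeable libraries would give 2.86% by chance. These libraries are parted by the batch, which each group holds evenly, so the share by chance can be lower. The shares can therefore not be judged against 2.86%.

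**Figure D2:**
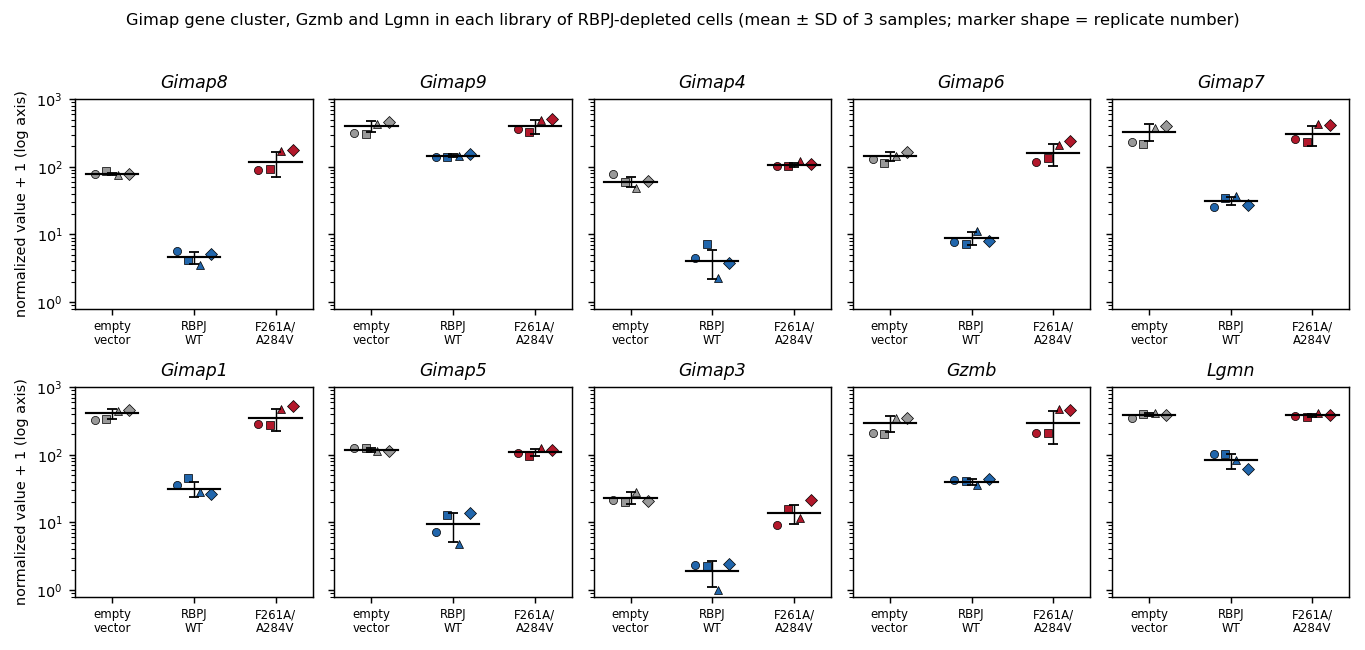
Normalized value + 1 (log axis) of the 8 tested Gimap genes, Gzmb and Lgmn in each of the 12 rescue libraries; marker shapes give the replicate number, and bars are mean ± SD over 3 samples, near-identical libraries counted once. The RBPJ WT libraries lie below those of both other groups for every gene drawn; Gimap8 averages 3.58 with RBPJ WT, 77.6 with the empty vector and 118 with the mutant.

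With RBPJ F261A/A284V, 2 genes differed from the empty vector. Rbpj rose to 778 ± 125 from 281 ± 32.1 (SD, n = 3 each), with log2 1.48 and adjusted p = 0.00114 in the fit to all 12 libraries. Ccdc80 rose to 244 ± 104 from 48.9 ± 9.59 (log2 2.39, adjusted p = 0.00255). Gimap8 averaged 118 ± 48.1 against 77.6 ± 3.01, Gzmb 295 ± 150 against 298.5 ± 81.1 (fitted log2 0.23, toward higher) and Lgmn 381 ± 22.6 against 392 ± 17.9, none of them past the test. L3mbtl3 averaged 672 ± 61.7 against 623 ± 17.5 (adjusted p = 1).

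None of the 20 tested Notch targets passed, over all genes or over the list alone, and camera gave an adjusted p = 0.942. Hes1 averaged 328 ± 93 against 289 ± 46.2, with an adjusted p of 0.0135 in the paired fit and 0.137 in the merged fit. The cell cycle list lay lower by camera (30 tested, 0 called over all genes or over the list alone, adjusted p = 0.00326; adjusted p = 0.902 with an estimated correlation). For the other 15 lists, of which only the Notch pathway held a called gene (Rbpj), camera gave adjusted p between 0.0703 and 0.942. No marker of another cell type passed.

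Limma called 2 genes up and 0 down of 11691 tested, with 240 genes at an unadjusted p under 0.05; edgeR called 2 up and 0 down, and DESeq2 5 up and 2 down. In the merged fit 6 rose and 5 fell, with Ccr4 and the proapoptotic gene Bcl2l11 among the former and Cd4 among the latter, and in the paired fit 47 rose and 29 fell, with Hes1, Ccr4, Bcl2l11 and Tnfrsf9 among the former and Cd4 and Cd28 among the latter. Within replicates 1 and 2 alone, where the empty vector libraries count as 1 sample, 7 rose and 8 fell, and within replicates 3 and 4 alone, where the mutant libraries count as 1 sample, 83 rose and 53 fell. With near-identical libraries merged and no batch term, only 1 gene rose.

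Compared directly with RBPJ WT, Gimap genes, Gzmb and Lgmn were higher with the mutant. Gimap8 was higher at 118 ± 48.1 against 3.58 ± 0.901 (log2 4.78, adjusted p = 3.4e-06), Gimap1 at 354 ± 128 against 30.5 ± 7.86 (log2 3.51), Gzmb at 295 ± 150 against 39 ± 4.09 (log2 2.96, adjusted p = 0.000583) and Lgmn at 381 ± 22.6 against 81.5 ± 20.4 (log2 2.18, adjusted p = 1.34e-05). Sgsh was lower at 56.8 ± 7.41 against 175 ± 6.6 (log2 -1.64, adjusted p = 7.33e-05). Rbpj did not pass the test, at 778 ± 125 with the mutant and 752 ± 101 with RBPJ WT (log2 0.17, SE 0.129, adjusted p = 1; 0.314 in the paired fit), although it was higher with the mutant in each same-numbered pair.

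Further genes higher with the mutant were Gimap4 (log2 4.74), Gimap6 (4.31), Gimap5 (3.65), Gimap7 (3.38), Cd6 (2.09, adjusted p = 0.0462) and the pseudogene Art2a-ps (4.91), which shares sequence with its parent gene. Lower with the mutant were the cadherin gene Fat1 (log2 -1.65), the signalling scaffold gene Card14 (-1.58), the adhesion receptor genes Adgrg1 (-1.17) and Adgrg3 (-0.89), Fam50b (-1.14), the fucosyltransferase gene Fut7 (-0.52), the phosphatase gene Ptpre (-0.45) and the lipase gene Lipe (-0.29). L3mbtl3 averaged 672 ± 61.7 with the mutant and 524 ± 30.6 with RBPJ WT (log2 0.38, adjusted p = 0.0511) and was higher in the merged fit (adjusted p = 0.00336) and in the paired fit (adjusted p = 0.000252).

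Of 20 Notch targets, Lgmn rose over all genes tested, 5 rose when adjusted over the list alone, and camera gave an adjusted p = 0.000912 (adjusted p = 0.0327 with an estimated correlation). The same 5 as fell with RBPJ WT rose in the merged fit (camera adjusted p = 0.000153; adjusted p = 0.0882 with an estimated correlation), among them Hes1 (328 ± 93 against 193 ± 40.3, adjusted p = 1.3e-07) and Notch1 (148 ± 51.9 against 46.5 ± 21.9, adjusted p = 1.34e-05). Spen was higher (log2 0.41, adjusted p = 0.0122; 1 of 17 corepressors). No interferon gene of 27 passed over all genes or over the list alone; camera placed that list higher (adjusted p = 0.000912; adjusted p = 0.593 with an estimated correlation). In the paired fit 6 of them rose (Ddx58, Gbp3, Ifi44, Ifih1, Isg15 and Rtp4) and 2 fell (Dhx58 and Usp18), and in the merged fit Ifih1 rose and Usp18 fell. For the other 14 lists camera gave adjusted p between 0.084 and 0.959. In the merged fit camera also placed higher the lists of glycolysis and hypoxia (adjusted p = 0.0022), T cell activation (0.0272) and histones (0.000153), with adjusted p = 0.768, 0.288 and 0.715 with an estimated correlation; in the paired fit, glycolysis and hypoxia had 0.00258 and histones 0.000231, and 0.738 for each with an estimated correlation. Egr1, Gzmb and Tnfrsf9 rose in the merged fit, and no glycolysis, hypoxia or histone gene did. Cd28 was higher and Cd4, Ccr2 and Cxcr6 lower with the mutant in the merged fit. No marker of another cell type passed over all genes, and Itgam was higher in the merged fit and Pecam1 lower. The paired fit also called Cd68, Maml3, Aph1b, Sfmbt1, Irf4, Ercc5 and Bcl2l11 higher and E2f2, Slc2a3, Bbc3 and Gadd45a lower, and 2 chemokine and adhesion genes higher and 3 lower. Of the genes named in that list, only Aph1b was also called in the merged fit.

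In all, 27 genes were higher and 10 lower with the mutant. In the merged fit 126 were higher and 103 lower, all 37 among them, in the paired fit 293 of 554 called genes were higher and the rest lower, and with near-identical libraries merged and no batch term 10 and 2. Within replicates 1 and 2, where RBPJ WT counts as 1 sample, these counts were 82 and 108, and within replicates 3 and 4, where the mutant counts as 1 sample, they were 425 and 394. Gimap8 was higher by 4.22 and 5.34 and Lgmn by 1.85 and 2.50 in the respective batches. The total of 37 dropped to 20 without F261A/A284V replicate 3, 22 without F261A/A284V replicate 4 and 24 without RBPJ WT replicate 3.

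**Figure D3:**
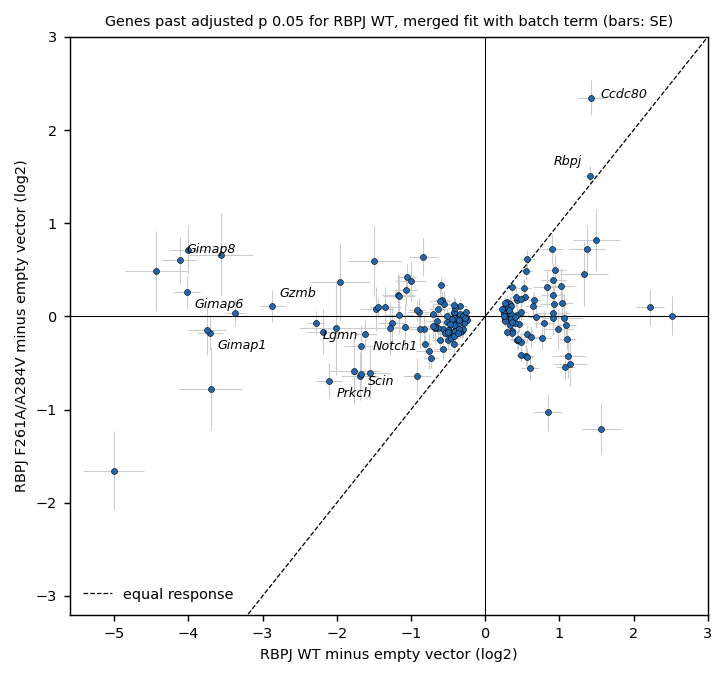
Log2 fold change against the empty vector with RBPJ WT (horizontal) and with RBPJ F261A/A284V (vertical) for the 178 genes called for RBPJ WT in the merged fit; grey bars are standard errors and the dashed line marks equal responses. These genes were chosen on the RBPJ WT response drawn, which overstates it; Gimap1, Gimap6, Gimap8, Gzmb and Lgmn lie far below 0 on the horizontal axis and near it on the vertical one, while Rbpj and Ccdc80 lie above the dashed line.

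The response to the mutant as a share of the response to RBPJ WT was measured over genes chosen and measured in different libraries. Over 117 genes chosen in replicates 1 and 2 the slope in replicates 3 and 4 was -0.0474, and over 145 genes chosen in replicates 3 and 4 the slope in replicates 1 and 2 was 0.0885. Their mean was 0.0205 (95% interval -0.0529 to 0.097, over genes and not libraries).

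The responses to both forms share their control libraries. Across genes, which are not independent replicates, their fold changes correlated at 0.167, where simulated unchanged groups against the same controls gave 0.501 on average and at most 0.546. The covariance was 0.00594 against 0.00792 simulated, and with the controls split between the comparisons the correlations were -0.0064 and -0.0387. The 2 genes up in both were Rbpj and Ccdc80, and none was down in both. Rbpj was put into both groups, so its rise in both was fixed by the design. Independent lists would share 0.000684 genes, but these lists share their controls, so that number may be too low a baseline. In the paired fit 8 genes were up in both (Ccdc80, Ccr4, Cd200r1, Ikzf3, Lztfl1, Pear1, Rbpj and Wwtr1) and 4 down (Cd28, Klhl30, Prkch and Scin), where independent lists would share 0.466 and 0.36 and the simulations 0. The simulated groups held no response, so they cannot show how many genes real responses would share through the controls.

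Genes called with the L3MBTL3 hairpin were followed in the rescue experiment, where 250 of those that rose and 129 of those that fell were tested. Lgmn and Pmm1, a phosphomannomutase, rose with the hairpin, fell with RBPJ WT and were higher with the mutant than with RBPJ WT. Independent lists would share 0.44 and 0.462 genes, and neither overlap of 2 passed (Fisher's exact test, 1-sided, p = 0.0708 and p = 0.0771; adjusted p = 0.231 for each over 12 overlaps). Pmm1 averaged 343 ± 14.3 with the hairpin against 245 ± 8.75 with scramble, and 179 ± 19.7 with RBPJ WT against 286 ± 10.8 with the empty vector and 271 ± 8.58 with the mutant. Among the 4 genes raised by RBPJ WT, Ccdc80 and Cd200r1 rose with the hairpin too (0.0881 for independent lists; Fisher's exact p = 0.00281, adjusted p = 0.0337), while Sgsh (80.9 ± 13.5 against 64.2 ± 31.9) and Rbpj did not pass there. The hairpin's L3mbtl3 values go against the label in 1 scramble library, so these directions are those of the labels.

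As sets, the genes that rose with the hairpin lay higher by camera with the mutant than with the empty vector (adjusted p = 0.000748) or RBPJ WT (adjusted p = 0.00656), and those that fell lay lower (adjusted p = 1.63e-07 and adjusted p = 7.05e-05). None of these calls held with an estimated correlation (adjusted p = 0.933 for both shifts of the first set, adjusted p = 0.11 and adjusted p = 0.171 for those of the other); after quantile scaling, the shift of the other set against the empty vector did (adjusted p = 0.0319). The median log2 fold changes were small, 0.05 and 0.04 for the first set and -0.06 and -0.06 for the other. Neither set was called with RBPJ WT against the empty vector (adjusted p = 0.954 for both). Within replicates 1 and 2 alone no shift with the mutant passed (adjusted p of 0.82, 0.762, 0.889 and 0.889), and the first set lay lower, not higher. Within replicates 3 and 4 alone, where the mutant libraries count as 1 sample, the same shifts had an adjusted p of 2.26e-07, 6.57e-05, 2.2e-14 and 1.29e-09, and of 0.0478, 0.07, 0.0417 and 0.0417 with an estimated correlation. The difference between the batches was not tested. The 20 genes lowered by RBPJ WT that were tested in the knockdown did not shift there as a set (adjusted p = 0.752), with a median of -0.04 where camera pointed up. The 85 genes lowered by RBPJ WT in the merged fit lay higher with the hairpin (adjusted p = 0.000358; adjusted p = 0.204 with an estimated correlation), and so did the 75 raised by it (adjusted p = 0.00177; adjusted p = 0.4 with an estimated correlation).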

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

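The batch term, each batch alone, the merged fits, removal of GC and length trends, edgeR with the block, and gene sets and lists from those fits were chosen only after the results were seen; the other alternatives were fixed before the data were examined. Of the 77 called results of named genes, none changed direction under the alternatives run for them, and all kept their call in the paired fit; named genes without a call were not followed. Calls were lost mostly by leaving out 1 of 4 knockdown libraries, by merging near-identical libraries without a batch term (21 of 38 rescue results kept) or by upper quartile scaling (57 of 77 kept). Where a count moved and nothing else is said, the cause was not tested.

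With the L3MBTL3 hairpin, 256 genes up and 129 down became 533 and 376 with quantile scaling, 1152 and 870 with library weights, 460 and 201 with DESeq2, and 136 up after GC and length removal. The count down was 78 without a filter and 85 with upper quartile scaling. Leaving out 1 library gave 0 to 644 up and 0 to 378 down. The replicate block, which takes out the spread shared by same-numbered libraries, gave 1566 and 1009, 1550 and 1040 with edgeR, and 1188 and 1595 with GC and length removed.

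For RBPJ WT against the empty vector, 4 up and 25 down became 116 and 145 with the replicate block, 153 and 173 with edgeR and the block, 141 and 169 with GC and length removal and the block, and 129 and 154 with the batch term. Replicates 1 and 2 alone gave 47 and 70, replicates 3 and 4 alone 64 and 81, the merged fit 78 and 100, and merging without the batch term 2 and 11. DESeq2 gave 21 and 39. The count up was 9 with quantile scaling, 8 with library weights and 7 with only the groups compared; the count down was 9 at a mean of at least 100, where fewer genes were tested. Leaving out 1 library gave 2 to 5 up and 15 to 21 down.

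For the mutant against the empty vector, 2 up and 0 down became 47 and 29 with the replicate block, 48 and 34 with edgeR and the block, 54 and 43 with GC and length removal and the block, 46 and 35 with the batch term, 7 and 8 in replicates 1 and 2, 83 and 53 in replicates 3 and 4, 6 and 5 in the merged fit and 5 and 2 with DESeq2. The count up was 6 without a filter, 1 with only the groups compared and 1 on merging without the batch term; the count down was 1 with quantile scaling. Leaving out 1 library gave 2 to 2 up and 0 to 1 down (limma; 240 genes at an unadjusted p under 0.05 with all libraries).

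For the mutant against RBPJ WT, 27 up and 10 down became 293 up and near 2.6e2 down (554 in all) with the replicate block, 290 and 254 with edgeR and the block, 368 and 361 with GC and length removal and the block, 305 and 293 with the batch term, 82 and 108 in replicates 1 and 2, 425 and 394 in replicates 3 and 4, 126 and 103 in the merged fit, 10 and 2 on merging without the batch term, 50 and 28 with DESeq2, 12 and 4 with only the groups compared and 12 and 6 at a mean of at least 100. Upper quartile scaling gave 6 down. Leaving out 1 library gave 15 to 24 up and 5 to 14 down.

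The lists past the threshold numbered 5 with the hairpin, 0 with an estimated correlation and 3 without scramble replicate 3. For RBPJ WT, 2 became 1 with an estimated correlation, 4 with the replicate block, 4 in the merged fit, and 4 and 7 in replicates 1 and 2 and 3 and 4. For the mutant against the empty vector, 1 became 0 with an estimated correlation and 2 in each batch. For the mutant against RBPJ WT, 2 became 1 with an estimated correlation, 4 with the replicate block, 5 in the merged fit, and 6 and 5 in the batches.

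The sets of hairpin genes had no call with RBPJ WT, and adjusted p of sets are given here. The set up with the hairpin turned from lower to higher there with the replicate block (0.832), quantile scaling (0.819), sets from the paired fit (0.324), the merged fit (0.824) and replicates 1 and 2 alone (0.82). The set down with it turned with the replicate block (0.977), at an absolute log2 fold change of at least 1 (0.526), with sets from the paired fit (0.297), the merged fit (0.824) and replicates 3 and 4 alone (0.973). With the mutant against the empty vector, the set up lost its call with an estimated correlation (0.933) and at a log2 fold change of at least 1 (0.462), and turned in replicates 1 and 2 (0.82); the set down lost it in the same settings (0.11, 0.462 and 0.889), but with an estimated correlation after quantile scaling it kept it (0.0319). With the mutant against RBPJ WT, the values were 0.933, 0.462, 0.432 with sets from the paired fit, and 0.762, reversed, in replicates 1 and 2 for the set up, and 0.171, 0.462 and 0.889 in replicates 1 and 2 for the set down. The genes down with RBPJ WT turned lower in the paired fit of the knockdown (0.476), and the larger sets from the paired and merged fits lay higher (9.95e-05 and 0.000358; 0.386 and 0.204 with an estimated correlation). So did the sets raised by RBPJ WT in these fits (3.96e-05 and 0.00177; 0.386 and 0.4 with an estimated correlation).

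The replicate block ended no call of a named gene; the calls it added among genes of the lists are given with the comparisons. The mutant's share of the RBPJ WT response stayed at 0.00968 with a pseudocount of 8 and at -0.00616 as a median ratio; other ways to split the replicates chose 0 genes by limma and gave no value. Depth limits low genes: with 3553505 reads in the shallowest library, 1 read is worth a value of 1.54.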

Other observations

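The tests of exchanged libraries, of GC content and gene length as the whole cause, of scramble replicate 3, of the batches, of the share of T cells and of the overlap with near-identical libraries counted once were chosen only after the result was seen.

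Among genes outside the lists, RBPJ WT also lowered Pla2g4e, a phospholipase gene, to 0.538 ± 0.659 from 48 ± 17.7 (SD, n = 3 each; log2 -4.90, adjusted p = 0.000727), and Ncald, which encodes a neuronal calcium sensor, to 49.8 ± 11.6 from 103 ± 9.1 (log2 -1.01, adjusted p = 0.0193). Both were chosen after their values were seen, and both adjusted p are from the fit to all 12 libraries. Across the tables, which were normalized separately and not tested against each other, Lgmn averaged 1.89 in scramble cells, 26.5 with the L3MBTL3 hairpin, 392 in RBPJ-depleted cells with the empty vector and 81.5 with RBPJ WT. Gzmb did not follow this order. It stood at 187, 174 and 190.5 in the scramble libraries and at 122, 94.2 and 149 with the hairpin. With RBPJ WT its values were lower than both, at 41.6, 39.3, 34.4 and 42.2. Gimap genes did not rise with the hairpin: Gimap7 (log2 -0.64), Gimap9 (-0.44) and Gimap1 (-0.40) fell in the paired fit.

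The RBPJ WT libraries were low in all 8 tested Gimap genes, which lie side by side in the reference annotation of the build GRCm38. Of the 5 nearest tested genes on either side, the medians were 0.03 and -0.166 on the log2 scale. These medians argue against loss of a chromosome segment that takes in most of those genes on either side. They cannot show a shorter one, and Tmem176b and Tmem176a beside the cluster were lower too (log2 -1.63 and -1.45, adjusted p = 0.0259 and 0.00178 in the paired fit). A loss that ends at these genes stays open, and Gimap9 fell less than the rest. Each group holds both batches in equal number, so the batch alone could not lower these genes with RBPJ WT. Of all genes called down in replicates 3 and 4, 96.3% were lower in replicates 1 and 2, so the decreases were not limited to 1 batch. Of the T cell identity genes, 75% changed by at most 0.178, which argues against fewer T cells in the cultures. In scramble cells, normalized separately and not tested against these, Gimap genes also varied between libraries. Gimap8 stood at 15.9, 17.25 and 92.2 in scramble replicates 1, 2 and 3, and Gimap4 at 7.49, 0 and 9.83. Gimap9 varied less (289, 297 and 456), and the cause of this spread was not tested. Reads shared between Gimap genes, and selection of a subclone in the RBPJ WT pool, stay open, the latter because the labels do not say that replicates were separate infections. A direct effect of RBPJ WT on the cluster was not tested and stays open too.

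Many genes were called with the L3MBTL3 hairpin although L3mbtl3 was hardly lower. Genes called in any 2 pairs kept their direction in the pair left out in 98.6%, 94.1% and 92.5% of cases, which argues against libraries exchanged within a pair; all 385 calls, 100%, were kept without scramble replicate 3, so that library is no source of them. With GC and length trends removed, 81.1% of the calls of the paired fit stayed and 18.9% were lost, so these trends may account for part of the calls but not for all; a first bound of 90% for this test was not met, and the bound of 50% used was set after the value was seen. Of the 10 splits of the 6 libraries, 1 gave as many calls, the real one with 385 (highest other 0), and 10 splits are too few for a share under 0.05. An effect of the hairpin on other transcripts, and a decrease of the L3MBTL3 protein larger than that of its transcript, stay open and untested.

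Genes that rose with the hairpin in the paired fit overlapped those higher with the mutant than with RBPJ WT: 106 were shared in the paired fits, where random sets matched on level and spread shared at most 65, and 46 in the merged fit, where they shared at most 32 (permutation p = 1e-04 for both, the smallest that 10000 draws can give). They also overlapped genes lower with the mutant: 58 in the paired fits (43.9 on average in matched sets, permutation p = 0.009) and 26 in the merged fit (19 on average, permutation p = 0.05). Genes were drawn singly, so these permutation p treat genes as independent and do not cover the spread between libraries. With GC and length trends removed, the overlap with genes higher with the mutant was 2.82 times that of independent lists, against 2.96 before, so neither property accounts for it. The 23 genes that also fell with RBPJ WT in the merged fit (at most 19 in matched sets) include the Notch genes Hes1, Jag1, Notch1, Aph1b and Lgmn, singled out after their values were seen. The same hairpin genes overlapped genes raised by RBPJ WT about as much (29 where independent lists share 10.1, beside 32 lowered where they share 11.5), and the shifts of the sets as a whole with the mutant passed within replicates 3 and 4, where the mutant is 1 sample and 1 of the 4 shifts fails with an estimated correlation, and did not pass within replicates 1 and 2; the difference was not tested. Genes that are variable in this line for other reasons stay open.

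Chance was examined by other splits of the rescue libraries. For RBPJ WT against the empty vector, 2 of 35 splits gave as many calls as the real 29, the other being the split into replicates 1 and 2 against 3 and 4 with 6589; for the mutant against the empty vector (real 2) and against RBPJ WT (real 37) it was also 2 of 35, with 6449 and 6023. This count does not by itself exclude chance. The other splits as large follow the batch and part no same-numbered pair, so their counts show the batch. With the block they called 3, 2 and 0 genes (limma). The block takes out the batch by construction, so this drop was fixed in advance and shows nothing further. For RBPJ WT, 100% and 96.3% of genes called down in one batch were lower in the other. This cannot settle chance, because the labels do not say that the batches came from separate infections. In replicates 1 and 2, each of these groups also counts as 1 sample. Among the 8 splits that part all pairs, the highest other count was 0 in limma, with and without the block. These 8 splits are too few for a share under 0.05. Some of them also set near-identical libraries in opposite groups, which by itself keeps counts low. The paired fit of the real split called 116 up and 145 down, 47 up and 29 down, and 554 in all. For the mutant against RBPJ WT, other splits that part only 2 pairs called as many as 158 and 207 genes with the block. They called 0 without it. Counts of that size with the block can thus arise from other groupings of the libraries.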
